A study of Mus musculus with 24 samples.

How the data were processed

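Livers of female B6C3F1 mice, a hybrid strain used in toxicology, were measured by RNA sequencing of total RNA from which ribosomal RNA had been removed with beads. Mice received furan by oral gavage at 8 mg per kg body weight per day in corn oil for 21 days, or corn oil alone, and tissue was taken 4 hours after the last dose. Furan is a heterocyclic compound formed when food is heated and is toxic to the rodent liver. Each liver was divided into 3 pieces: a piece snap frozen in liquid nitrogen, a piece kept in formalin for 18 hours before paraffin embedding (FFPE 18 h), and a piece kept in formalin for 3 weeks before embedding (FFPE 3 weeks). With 4 control and 4 furan animals this gave 6 groups of 4 libraries, 24 libraries in all. The labels give different extraction kits for frozen and fixed tissue and 2 sections in place of 1 for the 3-week samples. Preservation, extraction kit, input and the piece of liver can thus not be separated. Libraries were made with the TruSeq total RNA kit and sequenced on the HiSeq 2000.

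The authors list CASAVA 1.8.2, STAR 2.3.0 and featureCounts 1.4.4 with genome build mm9. The deposited table holds raw counts, 1 column per library, for 24015 gene symbols, of which 4185 had no count in any library. All values were whole numbers, no pair of columns was identical, and no normalization was found. The gene models, the strand setting and the handling of reads that map to several places are not stated, so reads of gene families such as the major urinary proteins and of small RNAs inside introns could be shared with, or taken from, their neighbours or hosts. Symbols of mitochondrially encoded genes were absent from the table. No coordinates are given, because the annotation at hand is for another build (GRCm38). That annotation served only for transcript length and GC content, which were found for 23640 symbols, 949 of them through a synonym.

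Counts were analysed in R 4.3.3 with edgeR 4.0.16: TMM normalization, filterByExpr, robust dispersion and the quasi-likelihood test, two-sided, with Benjamini-Hochberg adjusted p below 0.05 as the threshold for a call. Furan was compared with control within each preservation, 4 against 4 animals, each preservation fitted on its own. Preservations were compared as the mean over both treatments, 8 against 8 libraries, and the difference of the furan effect between preservations was tested as an interaction. The same animal numbers occur in each preservation, and the fit with the animal as replicate block was set as an alternative. Calls shared between preservations were counted among genes tested in both. Fold changes were correlated across genes, and because genes are not independent replicates no p is given for these correlations. Mixed splits of the animals, with 2 control and 2 furan animals in each part, gave the correlation that arises because the same animals are in each preservation. Measures of libraries were compared within animals by an exact permutation test over sign flips, two-sided, whose smallest possible p with 8 animals is 0.0078.

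Gene lists (37, for toxicity pathways, hepatocyte functions, the other cell types of liver and RNA classes) were tested with camera from limma 3.58.1 on log2 counts-per-million (CPM, prior count 2) with a preset inter-gene correlation of 0.01. The adjustment ran over all lists of a comparison with at least 3 tested members, and the test was repeated with a correlation estimated from the data. Member counts come from the edgeR test. The list of mitochondrially encoded genes had no member in the table. Named genes follow a rule. In fresh frozen tissue they are the 10 largest rises and 10 largest falls among genes with adjusted p below 0.05, a mean log2 CPM of at least 1 and no overlap between control and furan libraries. In FFPE 18 h and FFPE 3 weeks they are the 5 and 5 by the same rule. For preservation they are the 8 and 8 with no overlap of the libraries, for each interaction the 5 smallest p, and for each list up to 4 members with the smallest p. These tests, lists, rules and alternatives were fixed before the data were examined.

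CPM of named genes are normalized with TMM and given as mean ± SD of 4 animals, and log2 fold changes as estimate ± SE, where the SE is the estimate divided by the square root of its F statistic. Where a group had no count, the fold is a lower bound against a floor of 3 counts over the group. With 1 to 3 counts a ratio with its 95% counting interval is given. Such intervals and floors cover counting error only. Alternatives were DESeq2 size factors, no low-count filter, the DESeq2 1.42.0 test, a fold threshold of 1.5, leaving out each library (for overlaps and correlations, each animal from every preservation), thinning every library to 5560002 counts with seed 1, a fit over all 24 libraries and the replicate block. With the replicate block the calls were 8522 for FFPE 18 h versus frozen, 6719 for FFPE 3 weeks versus frozen and 5162 for FFPE 3 weeks versus FFPE 18 h, and 0 for each interaction. Corrections for GC content and transcript length, and list tests with these, with the block or without a library, were added after the data were seen. The pipeline was tested on simulated data with changed genes spiked into the groups. The share of spiked changes of 2-fold that edgeR called was 59.7% in frozen tissue, 80.6% in FFPE 18 h and 40.3% in FFPE 3 weeks. Only genes above a minimum mean count were spiked, and libraries were drawn independently, without animal effects. Such shares, also those for interactions, may thus be lower over all tested genes. Unchanged genes made up 8.18%, 9.09% and 1.15% of the edgeR calls, and 21.2%, 12.4% and 16.4% of the DESeq2 calls. No library was left out of the main tests.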

Results

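Gene expression was measured in liver of 4 control and 4 furan-dosed mice, in 3 pieces of each liver preserved in different ways, which gave 6 groups of 4 libraries. Total counts per library, in megacounts (M), were 38.0 to 49.3 M in fresh frozen tissue, 22.9 to 28.1 M in FFPE 18 h tissue and 5.56 to 11 M in FFPE 3 weeks tissue. Within a preservation the treatments were close, with 42.3 ± 3.64 M counts in control and 46.2 ± 2.41 M in furan frozen libraries (SD, n = 4). The FFPE 18 h libraries held 23.7 ± 1.11 and 25 ± 2.01 M, and the FFPE 3 weeks libraries 9.19 ± 1.90 and 9.03 ± 2.39 M. The first question was which genes furan changed in fresh frozen liver, and the next whether the same changes were measured in fixed tissue.

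In fresh frozen liver, the named rises with furan included p53 targets. Cdkn1a, a cell-cycle inhibitor induced by p53, rose 21.1-fold from 0.545 ± 0.251 to 11.7 ± 1.91 CPM (n = 4; log2 fold change 4.40 ± 0.29, adjusted p = 5.19e-05). Eda2r, a receptor of the tumour necrosis factor family and p53 target, rose 21.8-fold from 0.706 ± 0.412 to 15.7 ± 5.58 CPM (adjusted p = 0.000888). Mmp12, the macrophage elastase, rose 26.2-fold from 0.320 ± 0.209 to 8.68 ± 5.20 CPM (adjusted p = 0.00184). Elovl3, a fatty acid elongase, fell by 2.57 on the log2 scale, from 6.29 ± 4.02 to 1.05 ± 0.243 CPM (adjusted p = 0.0115). In total edgeR called 392 of 14122 genes, 222 higher and 170 lower, and 83.4% of them changed at least 1.5-fold.

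The named rises went on with Phlda3, a p53-induced repressor of Akt signalling, at a log2 fold change of 3.56 ± 0.38 (adjusted p = 0.00103). The uncharacterised 4632434I11Rik rose by 2.95 ± 0.19 (adjusted p = 5.19e-05). Cyp3a16, a cytochrome P450, rose by 2.79 ± 0.50 (adjusted p = 0.0155), and Ugt2b37, a glucuronosyltransferase, by 2.43 ± 0.52 (adjusted p = 0.0329). Mup20, a major urinary protein, rose 6.36-fold from 6.66 ± 3.50 to 42.4 ± 18.2 CPM. Atf3, a stress-induced transcription factor, rose 5.96-fold from 1.44 ± 0.812 to 8.64 ± 2.86 CPM. Ddit4l, an inhibitor of mTOR signalling, rose by 2.54 ± 0.59 on the log2 scale (adjusted p = 0.0458).

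Among the named falls, the transcript B930025P03Rik went from 12 ± 2.95 to 2.06 ± 0.729 CPM and Lect1, which encodes chondromodulin, from 6.78 ± 0.998 to 1.62 ± 0.331 CPM (adjusted p = 0.00103 and 0.000847). Bmf, a pro-apoptotic BCL2 family member, fell from 29.3 ± 4.42 to 9.26 ± 2.85 CPM. Rad51b, of the recombination repair machinery, fell from 12.6 ± 2.85 to 4.32 ± 0.789 CPM, and the synaptotagmin Syt3 from 4.29 ± 1.90 to 1.36 ± 0.117 CPM. Log2 fold changes of the remaining named falls were -1.83 ± 0.18 for 1500017E21Rik, -1.74 ± 0.28 for Cpsf4l, -1.71 ± 0.16 for 4833411C07Rik and -1.54 ± 0.18 for Pcp4l1.

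**Figure D1:**
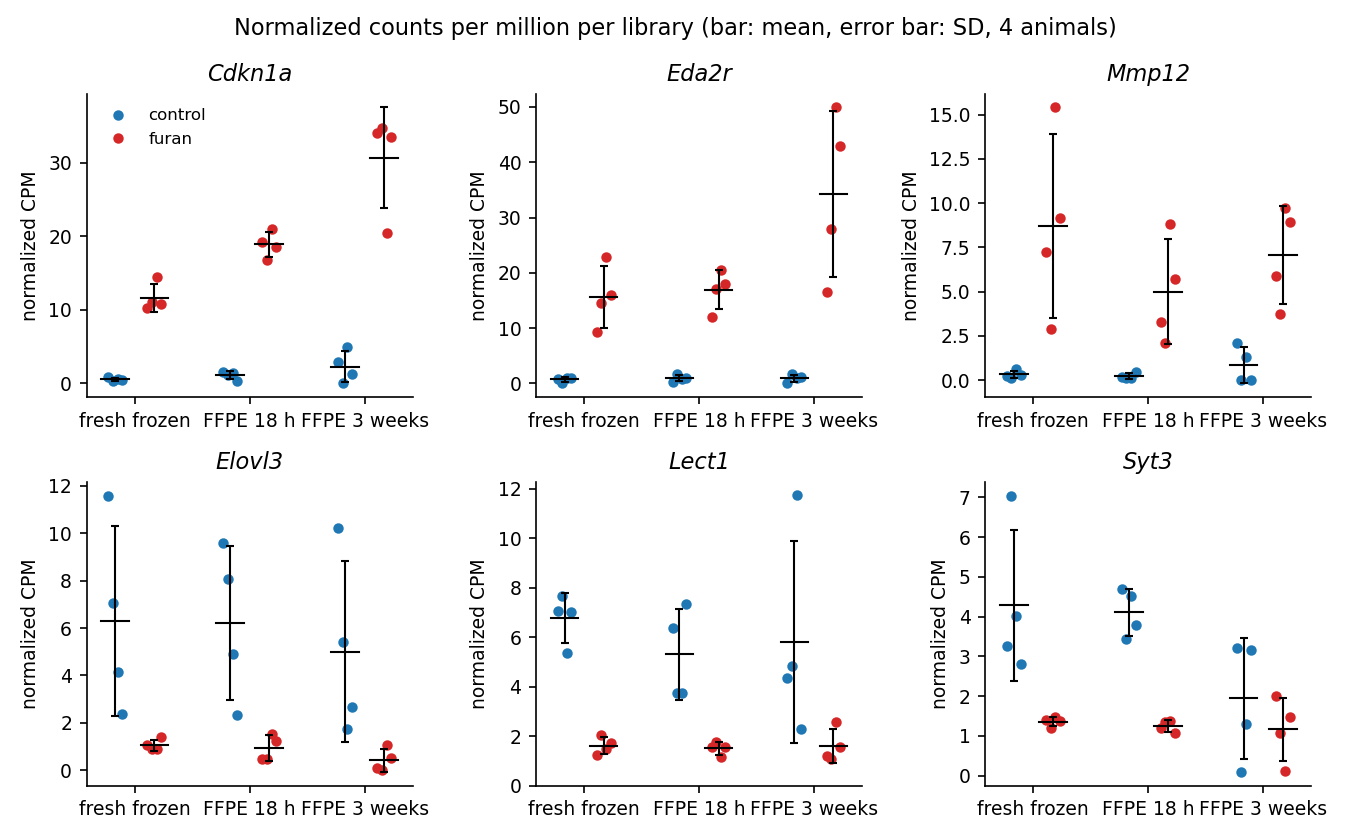
Normalized CPM of 6 named genes (vertical axis) in control and furan libraries of each preservation, with a point per library, a bar at the mean and the SD of 4 animals as error bar. Cdkn1a and Eda2r were higher with furan in each preservation, while Elovl3, Lect1 and Syt3 were lower with furan in frozen and FFPE 18 h tissue.

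The p53 target list rose as a set in frozen liver, with a median log2 fold change of 0.99 over 26 members (camera adjusted p = 5.81e-13). Of these, 13 rose, 0 fell and 13 did not pass, and 14 rose when adjusted over the list alone. It was also past the threshold with an estimated correlation (adjusted p = 0.0171). NRF2 targets, which encode enzymes of glutathione and quinone metabolism, had a median of 0.60 (adjusted p = 7.77e-13, adjusted p = 0.117 with an estimated correlation). Of 28 NRF2 targets 13 rose, 0 fell and 15 did not pass, and 19 rose when adjusted over the list alone. Gsta1 rose 6.26-fold (log2 2.65 ± 0.34), Srxn1 by 1.25 ± 0.15, Nqo1 by 1.21 ± 0.16 and Ephx1 by 1.05 ± 0.13.

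Of 16 heat shock genes 4 rose and 12 did not pass, 10 when adjusted over the list alone, with a median of 0.50 (adjusted p = 4.9e-08, adjusted p = 0.128 with an estimated correlation). Hsp90aa1 rose by 1.02 ± 0.19 and Hsph1 by 0.82 ± 0.14. Of 24 immediate early genes 4 rose, 8 when adjusted over the list alone, among them Jun at 5.05-fold (adjusted p of the list = 4.03e-05, adjusted p = 0.164 with an estimated correlation). Dusp6 rose by 1.59 ± 0.23 on the log2 scale and Btg2, which is also a p53 target, by 1.26 ± 0.13. Of 29 cytoskeleton and injury genes 4 rose, 3 of them tubulins, and 6 rose and 1 fell when adjusted over the list alone (adjusted p = 0.00263, adjusted p = 0.164 with an estimated correlation). Tubb2a rose 4.94-fold and the receptor Tnfrsf12a by 1.95 ± 0.23. The list of ER stress and the integrated stress response had a median of 0.20 over 25 members (adjusted p = 0.0272, adjusted p = 0.392 with an estimated correlation). In it Atf3, Atf4 (0.54 ± 0.09) and Psat1 (1.37 ± 0.31) rose while Trib3 fell by 1.12, and 5 rose and 2 fell when adjusted over the list alone.

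Cell cycle genes had a median of 0.74 over 39 members (adjusted p = 8.78e-11, adjusted p = 0.232 with an estimated correlation). Of these, 7 rose, 0 fell and 32 did not pass, and 19 rose when adjusted over the list alone, with Ccnb2 at 1.85 ± 0.30 and the proliferation marker Mki67 at 1.12 ± 0.22. Replication-dependent histones had 2 of 34 members higher, 4 when adjusted over the list alone, with a median of 0.01 (adjusted p = 0.0412, adjusted p = 0.704 with an estimated correlation). Of 15 oncofetal and liver tumour markers 5 rose, 7 when adjusted over the list alone (adjusted p = 0.00189, adjusted p = 0.128 with an estimated correlation). Among them the steroid reductase Akr1c18 rose 18.7-fold (4.23 ± 0.50) and H19, an imprinted fetal RNA, by 1.95 ± 0.46. Proteasome genes (median 0.12, adjusted p = 0.0287, adjusted p = 0.549 with an estimated correlation) and cytosolic ribosomal proteins (median 0.20, adjusted p = 0.00263, adjusted p = 0.375 with an estimated correlation) shifted upward as sets with 0 members called by edgeR. No member of either list was called when adjusted over the list alone.

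Pericentral hepatocyte markers fell as a set, with 3 of 22 members lower, 5 when adjusted over the list alone, and a median of -0.10 (adjusted p = 0.0183, adjusted p = 0.375 with an estimated correlation). Cyp2e1, which metabolises furan, fell by 0.71 ± 0.12 on the log2 scale (adjusted p = 0.0108), and Notum, a Wnt antagonist, by 1.00 ± 0.19. Fatty acid synthesis genes had 3 of 22 members lower, also when adjusted over the list alone, which were Elovl3, Dgat2 (-0.60 ± 0.14) and Acacb (-1.13 ± 0.27), and a median of -0.30 (adjusted p = 0.00263, adjusted p = 0.375 with an estimated correlation). Sets not past the threshold were periportal markers (median -0.09, 1 of 23 lower), cytochrome P450 and xenobiotic enzymes (-0.05, 3 higher and 3 lower of 37), bile acid genes (-0.09, 1 of 24 higher) and cholesterol biosynthesis (0.15, 0 of 25 called). PPAR alpha targets (-0.09, 0 of 29), nuclear genes of the respiratory chain (0.11, 0 of 50), secreted liver proteins (-0.09, 1 higher and 1 lower of 33) and major urinary proteins (0.17, 1 of 17 higher) did not pass either. Without control animal 3 secreted liver proteins passed downward (adjusted p = 0.0200 against 0.107). Within these, Cyp2a4 rose by 1.18 ± 0.14 and the bile acid transporter Slc10a2 by 1.35 ± 0.21, and Mup20 is in both of the latter lists. Adjusted over the list alone, 4 P450 and xenobiotic genes were higher and 5 lower, and 1 cholesterol gene was higher and 1 lower. The circadian clock list had a median of -0.26, a mean of 0.04 and no call as a set, with Arntl at 2.06 ± 0.40, and 5 higher and 4 lower members when adjusted over the list alone.

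Markers of sinusoidal endothelial cells fell as a set, with a median of -0.30 over 19 members (adjusted p = 2.24e-07, adjusted p = 0.0171 with an estimated correlation). Stab2, a scavenger receptor of these cells, was the 1 member called over all genes (-0.42 ± 0.10), and 10 fell when adjusted over the list alone. Quiescent stellate cell markers had a median of -0.15 with 0 of 13 members called (adjusted p = 0.0277, adjusted p = 0.164 with an estimated correlation). Inflammatory cytokines and chemokines had a median of 0.19 (adjusted p = 0.0277, adjusted p = 0.375 with an estimated correlation). Cxcl10 rose by 1.43 ± 0.22 and Icam1 by 0.67 ± 0.16, the 2 of 17 members called, and 5 rose and 1 fell when adjusted over the list alone. Markers of macrophages (median -0.31, 1 of 21 higher), lymphocytes (-0.15, 0 of 19), neutrophils (-0.21, 0 of 4), erythroid cells (-0.14, 0 of 5) and bile duct cells (0.04, 1 of 16 higher) did not pass as sets. The called macrophage marker was Hmox1, also an NRF2 target (1.39 ± 0.30, adjusted p = 0.0379), and the called bile duct marker was Prom1, also in the oncofetal list. Acute phase genes (0.04, 0 of 24) and the extracellular matrix and stellate activation list (-0.04, 1 of 27 higher) did not pass either. Among RNA classes, small nucleolar RNAs (-0.16, 0 of 57), microRNA precursors (0.01, 0 of 41), other small structured RNAs (-0.15, 0 of 6) and long nuclear RNAs (median -0.07, mean 0.03, 0 of 15) did not pass.

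The count of calls in frozen tissue depended on single libraries. It was 1148 without the library of control animal 3, whose expression stood apart from the other controls, and 1066 with DESeq2, while leaving out other libraries brought it to 99 without furan animal 44, 105 without 43, 160 without 42, 174 without 41, 146 without control animal 4 and 182 without 6. The 16 lists past the threshold were reached or exceeded in 2 of the 35 splits of these 8 animals, the real one included.

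**Figure D2:**
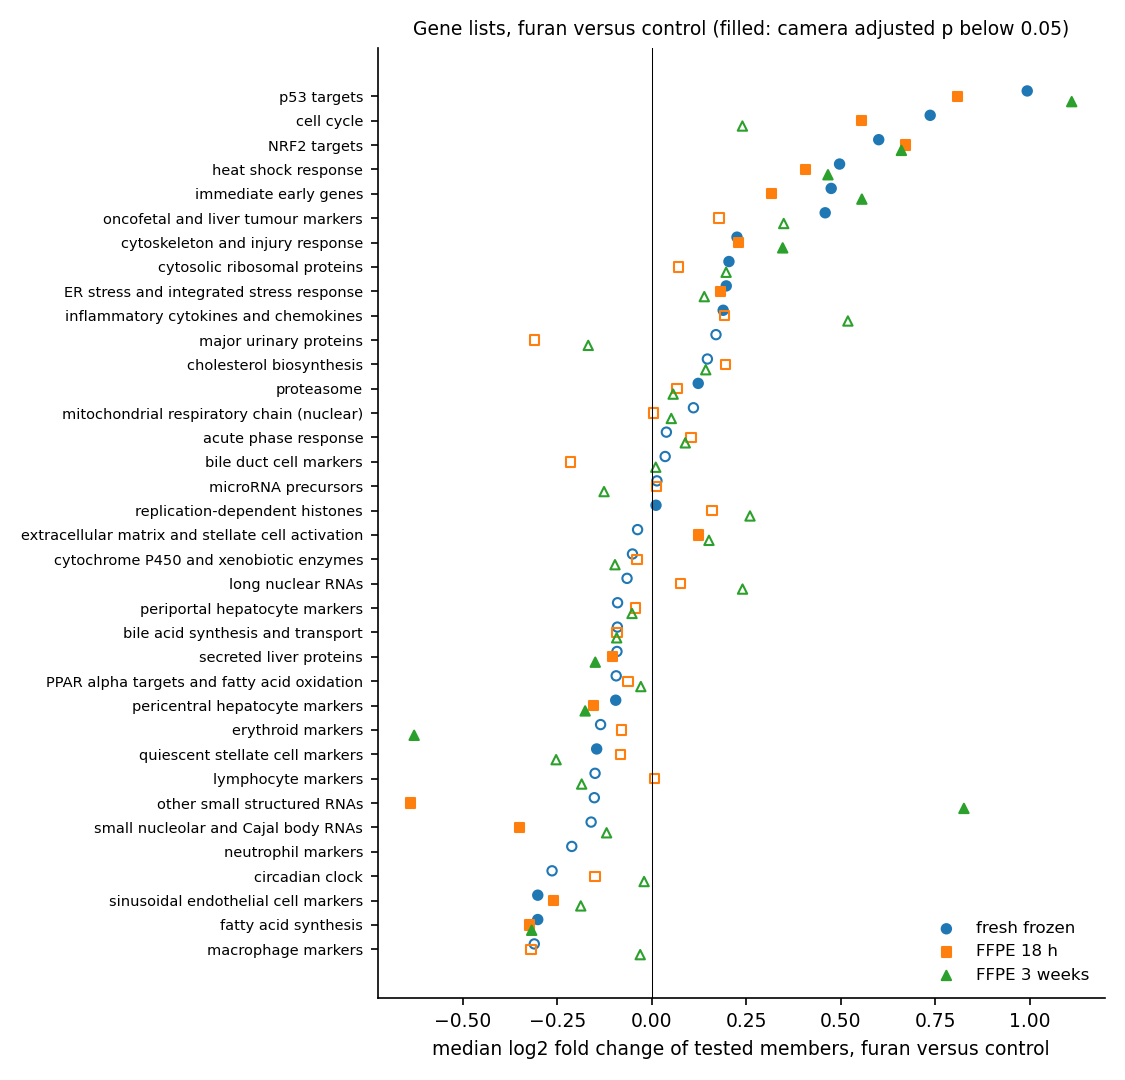
Median log2 fold change of furan against control over the tested members of each gene list (horizontal axis) in 3 preservations, with filled symbols where the camera adjusted p was below 0.05. The p53 and NRF2 target lists lay to the right of 0 and the fatty acid synthesis list to the left in each preservation.

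The comparison in FFPE 18 h tissue asked whether a usual fixation leaves the furan response measurable. More genes with small changes passed than in frozen tissue. Cdkn1a rose 17.3-fold from 1.08 ± 0.553 to 18.9 ± 1.72 CPM (n = 4, log2 4.11 ± 0.27, adjusted p = 1.37e-06) and Eda2r 17.1-fold from 0.974 ± 0.598 to 16.9 ± 3.53 CPM (adjusted p = 7.48e-05). Mmp12 rose 21.7-fold from 0.227 ± 0.174 to 4.98 ± 2.97 CPM, Dusp8, a phosphatase of stress kinases, 13.1-fold from 0.375 ± 0.163 to 4.97 ± 1.55 CPM, and Hapln1, a hyaluronan link protein, 9.85-fold (adjusted p = 0.000468). Elovl3 fell from 6.22 ± 3.24 to 0.929 ± 0.548 CPM, B930025P03Rik from 22.3 ± 2.09 to 3.69 ± 1.43 CPM and Syt3 from 4.11 ± 0.596 to 1.25 ± 0.140 CPM. Lect1 fell by 1.81 ± 0.27 on the log2 scale and 1500017E21Rik by 1.71 ± 0.20. In all, 2208 of 14204 genes were called, 1111 higher and 1097 lower, and 26.7% of them changed at least 1.5-fold.

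Of 29 NRF2 targets 20 rose, 0 fell and 9 did not pass, 21 when adjusted over the list alone, with a median of 0.67 (adjusted p = 2.65e-11, adjusted p = 0.175 with an estimated correlation). Srxn1 rose by 1.35 ± 0.09 and Ephx1 by 1.15 ± 0.08. Of 26 p53 targets 16 rose and 1 fell, 17 and 1 when adjusted over the list alone, with a median of 0.81 (adjusted p = 1.38e-11, adjusted p = 0.0492 with an estimated correlation), and Zmat3 rose by 1.63 ± 0.11 and Ccng1 by 1.17 ± 0.07. Heat shock genes rose in 10 of 16 cases, 12 when adjusted over the list alone (median 0.41, adjusted p = 4.58e-08, adjusted p = 0.175 with an estimated correlation). Cell cycle genes rose in 7 of 38 cases, also when adjusted over the list alone (median 0.56, adjusted p = 0.000281, adjusted p = 0.516 with an estimated correlation). Tpx2 rose by 1.70 ± 0.33. Immediate early genes had 4 higher and 1 lower of 24, also when adjusted over the list alone (adjusted p = 0.0156, adjusted p = 0.378 with an estimated correlation). The ER stress list had 5 higher and 1 lower of 25, 6 and 1 when adjusted over the list alone (adjusted p = 0.0152, adjusted p = 0.393 with an estimated correlation). Cytoskeleton and injury genes had 7 of 28 higher, 9 when adjusted over the list alone (adjusted p = 0.000918, adjusted p = 0.393 with an estimated correlation). Matrix and stellate activation genes had 3 of 27 higher, also when adjusted over the list alone (median 0.12, adjusted p = 0.0446, adjusted p = 0.757 with an estimated correlation). Col3a1 rose by 0.31 ± 0.09.

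Sinusoidal endothelial markers fell in 11 of 19 cases, 15 when adjusted over the list alone, with a median of -0.26 (adjusted p = 8.04e-06, adjusted p = 0.175 with an estimated correlation). Flt4 fell by 0.39 ± 0.08. Pericentral markers fell in 8 of 22 cases, and when adjusted over the list alone 8 fell and 1 rose (adjusted p = 0.00543, adjusted p = 0.516 with an estimated correlation). Cyp2e1 fell by 0.63 ± 0.07. Fatty acid synthesis genes fell in 7 of 22 cases, and when adjusted over the list alone 7 fell and 1 rose (adjusted p = 0.00285, adjusted p = 0.523 with an estimated correlation). Secreted liver proteins had 12 lower and 1 higher of 33, 13 and 1 when adjusted over the list alone, with Fetub at -0.53 ± 0.07 (adjusted p = 0.0152, adjusted p = 0.757 with an estimated correlation). Small nucleolar RNAs were lower in 11 of 67 cases, 14 when adjusted over the list alone, with Snora23 at -0.50 ± 0.08 (adjusted p = 0.000392, adjusted p = 0.484 with an estimated correlation). Other small structured RNAs had a median of -0.64 with 0 of 7 called (adjusted p = 0.0491, adjusted p = 0.516 with an estimated correlation). The remaining 21 tested lists did not pass, among them inflammatory cytokines (adjusted p = 0.0524) and oncofetal markers (adjusted p = 0.223). Medians and means of lists not past the threshold differed in sign for the circadian clock (-0.15 and 0.10), histones (0.16 and -0.05), respiratory chain (0.01 and -0.02), erythroid (-0.08 and 0.04) and lymphocyte (0.01 and -0.09) lists. With a fold threshold of 1.5 there were 589 calls, and with a fit over all 24 libraries 305.

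The comparison in FFPE 3 weeks tissue asked the same of a prolonged fixation, with the fewest counts. Eda2r rose 36.8-fold from 0.930 ± 0.674 to 34.3 ± 15.0 CPM (n = 4, log2 5.20 ± 0.60, adjusted p = 6.88e-05). Hapln1 rose 34.3-fold from 0.260 ± 0.521 to 10.1 ± 5.94 CPM (adjusted p = 0.00698) and Cdkn1a 13.8-fold from 2.27 ± 2.14 to 30.6 ± 6.86 CPM (adjusted p = 0.0488). Slc7a11, a cystine and glutamate antiporter, had 0 counts in controls and 167 with furan, at least 55.2-fold higher (adjusted p = 0.0091). The uncharacterised 2810008D09Rik had 192 counts in controls and 1 with furan, a ratio of 193 with an interval of 34.3 to 7681 (adjusted p = 0.00693). Without TMM normalization, CPM of 2810008D09Rik in the same animals ran from 1.47 to 2.51 in control and 1.26 to 1.74 in furan frozen libraries. In FFPE 18 h they ran from 2.05 to 2.80 and from 1.46 to 2.82, and the gene was called in neither tissue. Adra1a, an alpha-adrenergic receptor, fell from 18.8 ± 5.05 to 3.96 ± 1.45 CPM, B930025P03Rik from 34.4 ± 1.78 to 5.75 ± 4.09 CPM, D430041D05Rik from 15.2 ± 3.56 to 3.72 ± 1.34 CPM and 1700028E10Rik from 12.9 ± 4.42 to 2.06 ± 1.48 CPM. In all, 335 of 12983 genes were called, 139 higher and 196 lower, and 66.3% of them changed at least 1.5-fold.

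Of 26 p53 targets 8 rose, 0 fell and 18 did not pass, 13 when adjusted over the list alone, with a median of 1.11 (adjusted p = 2.23e-11, adjusted p = 0.00689 with an estimated correlation), and Trp53inp1 rose by 1.25 ± 0.13. Of 21 immediate early genes 4 rose, 6 when adjusted over the list alone (median 0.56, adjusted p = 6.73e-07, adjusted p = 0.0341 with an estimated correlation). Dusp6 rose by 1.86 ± 0.15 and Jun by 1.99 ± 0.29. Of 27 NRF2 targets 9 rose, 11 when adjusted over the list alone (median 0.66, also with Slc7a11 at its bound, adjusted p = 1.78e-09, adjusted p = 0.0806 with an estimated correlation). Gclc rose by 0.84 ± 0.10 and Osgin1 by 1.71 ± 0.20. Heat shock genes had 0 of 16 members called and 5 higher when adjusted over the list alone (median 0.47, adjusted p = 3.62e-05, adjusted p = 0.0806 with an estimated correlation). Cytoskeleton and injury genes had 5 higher and 1 lower of 25, 6 and 1 when adjusted over the list alone, with Myh9 at 0.62 ± 0.11 (adjusted p = 0.0182, adjusted p = 0.283 with an estimated correlation). Other small structured RNAs had a median of 0.83 with 0 of 8 called and 1 higher when adjusted over the list alone (adjusted p = 0.022, adjusted p = 0.325 with an estimated correlation).

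Fatty acid synthesis genes fell in 4 of 22 cases, 9 when adjusted over the list alone (median -0.32, adjusted p = 6.6e-05, adjusted p = 0.283 with an estimated correlation). Mlxipl fell by 0.66 ± 0.12 and Dgat2 by 0.54 ± 0.11. Pericentral markers fell in 4 of 21 cases, 7 when adjusted over the list alone (adjusted p = 0.0294, adjusted p = 0.437 with an estimated correlation). Cyp2e1 fell by 0.77 ± 0.08 and Glul by 0.46 ± 0.09. Secreted proteins had 6 lower and 1 higher of 33, and 10 lower and 2 higher when adjusted over the list alone (adjusted p = 0.0195, adjusted p = 0.67 with an estimated correlation). Erythroid markers had a median of -0.63 with 0 of 4 called (adjusted p = 0.0321, adjusted p = 0.268 with an estimated correlation). Cell cycle genes (median 0.24, 0 of 30 called) and sinusoidal endothelial markers (median -0.19, 0 of 19 called) did not pass. Signs of median and mean differed for lymphocyte (-0.19 and 0.04), macrophage (-0.03 and 0.12), bile acid (-0.09 and 0.01) and major urinary protein (-0.17 and 0.01) lists, and bile duct markers had a median of 0.01 with the test downward. The count of calls was 218 without furan animal 44, 222 at a fold threshold of 1.5 and 1549 in a fit over all 24 libraries.

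The furan effects were then compared between preservations. Of 391 frozen calls tested in both, 331 (84.7%) were also called in FFPE 18 h and 136 of 371 (36.7%) in FFPE 3 weeks. Independent calls would share 31.1 and 4.75 genes in the same direction. Of the 335 calls in FFPE 3 weeks, 285 (85.1%) were called in FFPE 18 h. Each shared call had the same direction, and 132 genes, 60 higher and 72 lower, were called in all 3 preservations. Cdkn1a, Eda2r, Mup20 and Jun rose in each, as did 4632434I11Rik, while Bmf, Cyp2e1, Adra1a and B930025P03Rik fell in each. Mmp12, Phlda3, Atf3, Elovl3, Lect1, Syt3 and Rad51b were called in frozen and FFPE 18 h tissue. In FFPE 3 weeks their log2 fold changes were 3.04 ± 1.06, 3.26 ± 1.01, 2.64 ± 1.01, -3.49 ± 1.29, -1.84 ± 0.91, -0.73 ± 1.54 and -0.50 ± 0.38.

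Across genes, fold changes correlated with r = 0.70 between frozen and FFPE 18 h, 0.44 between frozen and FFPE 3 weeks and 0.44 between both fixations. Furan fold changes also followed GC content, with Spearman rho of -0.38 in frozen, -0.24 in FFPE 18 h and -0.06 in FFPE 3 weeks tissue. A GC trend of the same sign may thus be part of these correlations, above all of that between frozen and FFPE 18 h. The animals were the same in each preservation, and mixed splits of them gave a median r of 0.205, 0.0846 and 0.0862. With no low-count filter the correlations were 0.193, 0.121 and 0.113. With an animal left out of every preservation, the overlap of frozen with FFPE 18 h was 761 without control animal 3, 95 without furan animal 44, 100 without 43, 150 without 42, 157 without 41, 135 without control animal 4 and 172 without 6. With only the frozen library of control animal 3 left out, 852 of the 1148 frozen calls were also called in FFPE 18 h. The overlap of frozen with FFPE 3 weeks, again with the animal left out of every preservation, was 186 without control animal 3, 41 without furan animal 44, 44 without 43, 63 without 42, 59 without 41, 57 without control animal 4 and 77 without 6.

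**Figure D3:**
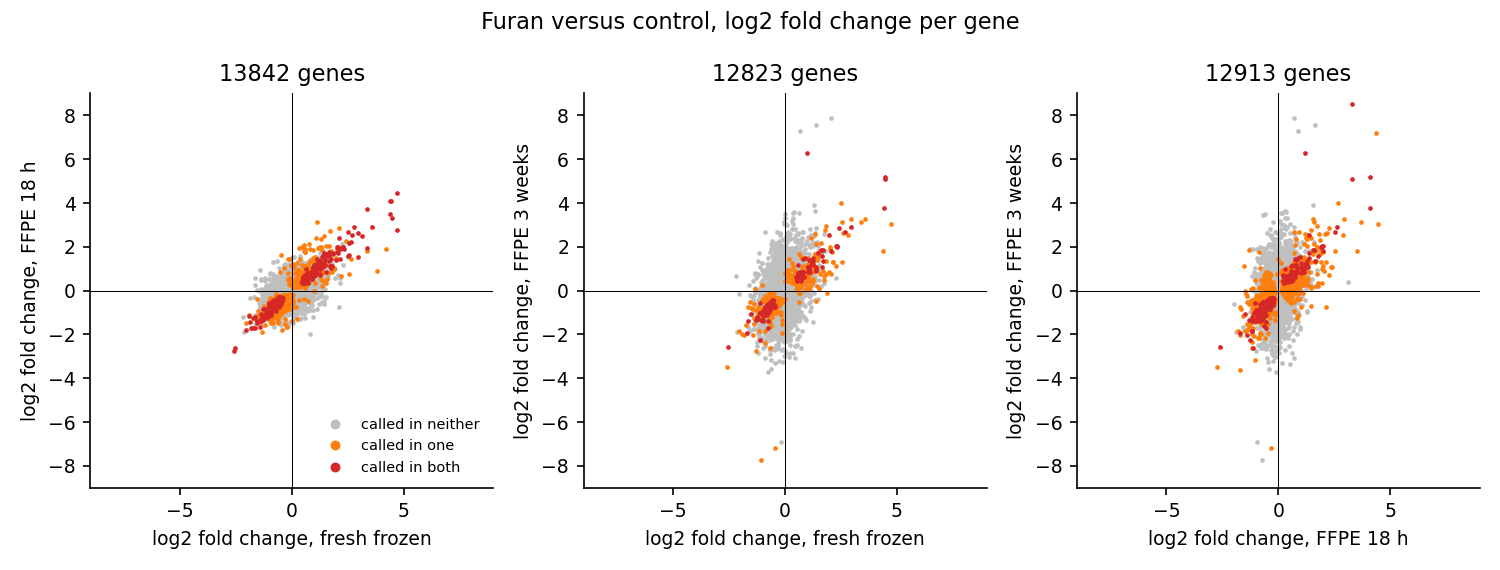
Log2 fold change of furan against control in 2 preservations per panel, a point per gene, coloured by whether edgeR called it in neither, one or both. The panels hold 13842, 12823 and 12913 genes, and genes called in both lie in the quadrants where both changes have the same sign.

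Tested as an interaction, 0 genes differed in their furan effect between any pair of preservations with edgeR. At an unadjusted p below 0.05 there were 239 genes for FFPE 18 h against frozen, 585 for FFPE 3 weeks against frozen and 766 for FFPE 3 weeks against FFPE 18 h, and DESeq2 called 0, 9 and 26. In the simulated data edgeR called 58.2%, 28.4% and 34.3% of 2-fold differences and 5.97%, 1.49% and 4.48% of 1.5-fold differences, so 0 calls do not show that the effects were equal. Differences of the log2 effect from frozen were -0.26 ± 0.42 for Cdkn1a, -0.33 ± 0.62 for Eda2r and -0.25 ± 0.99 for Mmp12 in FFPE 18 h, and 1.04 ± 0.44 for Rad51b in FFPE 3 weeks (adjusted p = 1.00). The smallest p for FFPE 18 h against frozen were those of Snora28 (-1.16 ± 0.27), Acmsd, 4930524O05Rik, Pdzd4 and Efcc1, each with adjusted p = 1.00. For FFPE 3 weeks against frozen they included those of 2810008D09Rik (adjusted p = 0.135), Crip1 (0.152), Gm11992 (0.27) and Nudt21 (0.853). For FFPE 3 weeks against FFPE 18 h they included those of 2810008D09Rik and Crip1, then Ninj1 (0.83 ± 0.18) and Rps15 (1.35 ± 0.31).

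Preservation itself was compared over both treatments, to show which transcripts were higher or lower in libraries of fixed tissue. Each preservation was a different piece of the liver, so such differences cannot be credited to fixation alone. In FFPE 18 h against frozen tissue, small nucleolar RNAs rose as a set and proteasome genes and secreted proteins fell. Snora3, a small nucleolar RNA, rose by 5.15 ± 0.13 on the log2 scale (8 against 8 libraries, adjusted p = 2e-16), the vault RNA Vaultrc5 by 5.22 ± 0.20 and the spliceosomal Rnu11 by 4.33 ± 0.25. Snora81 (4.96 ± 0.30), Snora23 (3.82 ± 0.18), Mir6236 (3.64 ± 0.44) and Snora28 (3.57 ± 0.14) followed. Dmbt1, a mucosal scavenger receptor, rose by 9.04 ± 1.12. Its CPM, here without TMM normalization, ran from 1.03 to 186 in FFPE 18 h and from 0 to 0.677 in frozen libraries. In FFPE 3 weeks libraries it ran from 0.0947 to 24.3, so the rise was not larger after longer fixation. Atp5k, of the mitochondrial ATP synthase, fell by 1.59 ± 0.09 (adjusted p = 9.04e-11), Snrpd2 by 1.43 ± 0.23, Pet100 by 1.38 ± 0.11 and Rarres2 by 1.34 ± 0.09. The fatty acid binding protein Fabp1 fell by 1.34 ± 0.10 (adjusted p = 1.31e-09), and Gm5549, Fgl1 (-1.32 ± 0.17) and Pole3 were the other named falls. In all, 8006 of 14843 genes were called, 3952 higher and 4054 lower.

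Of 75 small nucleolar RNAs 48 rose and 0 fell, 49 when adjusted over the list alone (median 1.02, adjusted p = 3.72e-11, adjusted p = 0.00891 with an estimated correlation). Other small structured RNAs had 4 of 8 higher and did not pass as a set (median 0.84, adjusted p = 0.0611). Of 76 microRNA precursors 41 rose, also when adjusted over the list alone (median 1.29, adjusted p = 1.28e-05, adjusted p = 0.0601 with an estimated correlation). Matrix and stellate activation genes had 16 of 28 higher and 2 lower, also when adjusted over the list alone (adjusted p = 0.00307, adjusted p = 0.278 with an estimated correlation). Acta2 rose by 2.48 ± 0.24 and Col1a1 by 2.31 ± 0.15. Of 50 respiratory chain genes 47 fell, also when adjusted over the list alone (median -0.87, adjusted p = 8.6e-18, adjusted p = 0.0601 with an estimated correlation). Of 33 secreted proteins 31 fell and 1 rose, also when adjusted over the list alone (median -0.76, adjusted p = 2.24e-14, adjusted p = 0.0417 with an estimated correlation). Apoh fell by 1.11 ± 0.07 and Ttr by 1.03 ± 0.07. Of 31 proteasome genes 28 fell and 1 rose, 29 and 1 when adjusted over the list alone (median -0.88, adjusted p = 2.63e-13, adjusted p = 0.0242 with an estimated correlation). Of 23 periportal markers 20 fell, also when adjusted over the list alone (adjusted p = 9.84e-07, adjusted p = 0.0242 with an estimated correlation). The remaining 14 lists past the threshold fell, with medians of -0.79 for acute phase genes, -0.80 for histones, -0.76 for major urinary proteins, -0.64 for P450 and xenobiotic enzymes, -0.56 for bile acid genes and -0.52 for macrophage markers and for cytoskeleton genes. Medians were -0.50 for PPAR alpha targets, -0.46 for cholesterol biosynthesis, -0.44 for heat shock genes and for cytosolic ribosomal proteins, -0.38 for pericentral markers, -0.33 for ER stress and -0.30 for NRF2 targets. None of these 14 passed with an estimated correlation (adjusted p from 0.0667 to 0.445).

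In FFPE 3 weeks against frozen tissue Snora69 rose by 8.05 ± 0.32, Rnu12 by 7.47 ± 0.47, Snora3 by 7.03 ± 0.15 (adjusted p = 8.16e-22), Snora81 by 6.89, Rnu11 by 6.87, Vaultrc5 by 6.75, Snora28 by 6.02 and Rprl2 by 5.92 ± 0.61. The replication factor Mcm5 fell by 3.25 ± 0.69 (adjusted p = 0.000335), Hist2h2bb by 3.06 ± 0.80, the adipokine Rarres2 by 2.74 ± 0.14, Vmo1 by 2.67, Thyn1 by 2.62, Nprl2 by 2.60 ± 0.33, 4632427E13Rik by 2.58 and H2-Q2 by 2.55. The lymphocyte markers Ltb and Cd3g had 0 counts in FFPE 3 weeks against 237 and 194, at least 21.7-fold and at least 17.8-fold lower, and Ube2c had 1 count against 369, a ratio of 102 with an interval of 18.1 to 4023. In all, 6952 of 14253 genes were called, 3275 higher and 3677 lower.

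Of 78 small nucleolar RNAs 59 rose, 64 when adjusted over the list alone (median 2.67, adjusted p = 7.82e-21, adjusted p = 9.57e-05 with an estimated correlation). Of 58 microRNA precursors 34 rose and 2 fell, also when adjusted over the list alone (median 2.57, adjusted p = 0.000625, adjusted p = 0.0345 with an estimated correlation). Of 15 long nuclear RNAs 8 rose, 10 when adjusted over the list alone (adjusted p = 0.000472, adjusted p = 0.0845 with an estimated correlation). Kcnq1ot1 rose by 2.57 ± 0.14, Neat1 by 2.25 ± 0.12 and Malat1 by 1.93 ± 0.08. Of 33 secreted proteins 32 fell and 1 rose, also when adjusted over the list alone (median -1.48, adjusted p = 4.19e-18, adjusted p = 0.0183 with an estimated correlation). Ambp fell by 2.05 ± 0.07. Respiratory chain genes fell in 47 of 50 cases, also when adjusted over the list alone (median -1.28, adjusted p = 3.18e-17, adjusted p = 0.0101 with an estimated correlation). Proteasome genes fell in 29 of 31, also when adjusted over the list alone (median -1.41, adjusted p = 5.78e-13, adjusted p = 0.00843 with an estimated correlation). Periportal markers (median -1.03, adjusted p = 0.00543 with an estimated correlation), bile acid genes (-0.84, adjusted p = 0.025 with an estimated correlation) and histones (-1.59, adjusted p = 0.0478 with an estimated correlation) fell too. Cps1 fell by 1.27 ± 0.07, Slc27a5 by 1.75 ± 0.07 and Hist1h1e by 2.03 ± 0.23. The other 15 lists past the threshold, 24 in all, did not pass with an estimated correlation (adjusted p from 0.0654 to 0.465). Of these, other small structured RNAs (median 1.36), immediate early genes (0.64) and the circadian clock (0.50) were higher, and acute phase genes (-1.48), P450 and xenobiotic enzymes (-0.91), cytoskeleton genes (-0.84), heat shock genes (-0.78), pericentral markers (-0.75) and PPAR alpha targets (-0.73) were lower. Macrophage markers (-0.70), cell cycle genes (-0.53), NRF2 targets (-0.47), cytosolic ribosomal proteins (-0.45), ER stress genes (-0.43) and cholesterol biosynthesis (-0.40) were lower as well. Lymphocyte markers did not pass as a set (median 0.03, also with Ltb and Cd3g at their bounds, mean -0.84).

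In FFPE 3 weeks against FFPE 18 h tissue, Rprl2 rose by 5.23 ± 0.55, Snora69 by 3.36 ± 0.18 and Snord8 by 3.25. Snora75 rose by 2.86, 5730408K05Rik by 2.84, Snora31 by 2.82 and Snora21 by 2.66. Counts of Lars2, the mitochondrial leucyl-tRNA synthetase, rose by 2.67 ± 0.13 (adjusted p = 2.12e-10). Lars2 CPM, here without TMM normalization, ran from 261 to 437 in FFPE 18 h and from 1832 to 2755 in FFPE 3 weeks. Rn45s, the ribosomal RNA precursor, ran from 8673 to 14922 and from 27688 to 51620 CPM. Among frozen libraries both were highest in control animal 3. Whether ribosomal RNA reads were counted under Lars2 was not tested, so a rise of its mRNA is not shown. Igflr1 fell by 3.58 ± 0.76, 4933411K16Rik by 2.76, Zfp109 by 2.40, Rccd1 by 2.27, Nprl2 by 1.99, Neil1 by 1.99, Htra2 by 1.82 and Ugt1a2 by 1.77. Of 80 small nucleolar RNAs 50 rose, and when adjusted over the list alone 54 rose and 1 fell (median 1.59, adjusted p = 3.58e-22, adjusted p = 0.0013 with an estimated correlation). Long nuclear RNAs rose in 9 of 15 cases, also when adjusted over the list alone (adjusted p = 3.35e-05, adjusted p = 0.0302 with an estimated correlation). Malat1 rose by 1.16 ± 0.05. Proteasome genes fell in 24 of 31 cases, also when adjusted over the list alone (median -0.62, adjusted p = 2.08e-08, adjusted p = 0.0302 with an estimated correlation). Secreted proteins fell in 28 of 33 cases and rose in 1, 29 and 1 when adjusted over the list alone (median -0.69, adjusted p = 4.35e-16, adjusted p = 0.0719 with an estimated correlation). Apoe fell by 1.03 ± 0.05. Immediate early genes rose in 7 of 24 cases, also when adjusted over the list alone (median 0.66, adjusted p = 0.00309, adjusted p = 0.0674 with an estimated correlation). Jund rose by 1.89 ± 0.14. The other 7 lists past the threshold had adjusted p from 0.0546 to 0.604 with an estimated correlation. Their medians were 1.45 for other small structured RNAs, -0.67 for acute phase genes, -0.48 for the respiratory chain, -0.47 for bile acid genes, -0.36 for P450 and xenobiotic enzymes, -0.34 for periportal markers and -0.20 for PPAR alpha targets. In all, 4664 of 14414 genes were called, 2142 higher and 2522 lower.

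**Figure D4:**
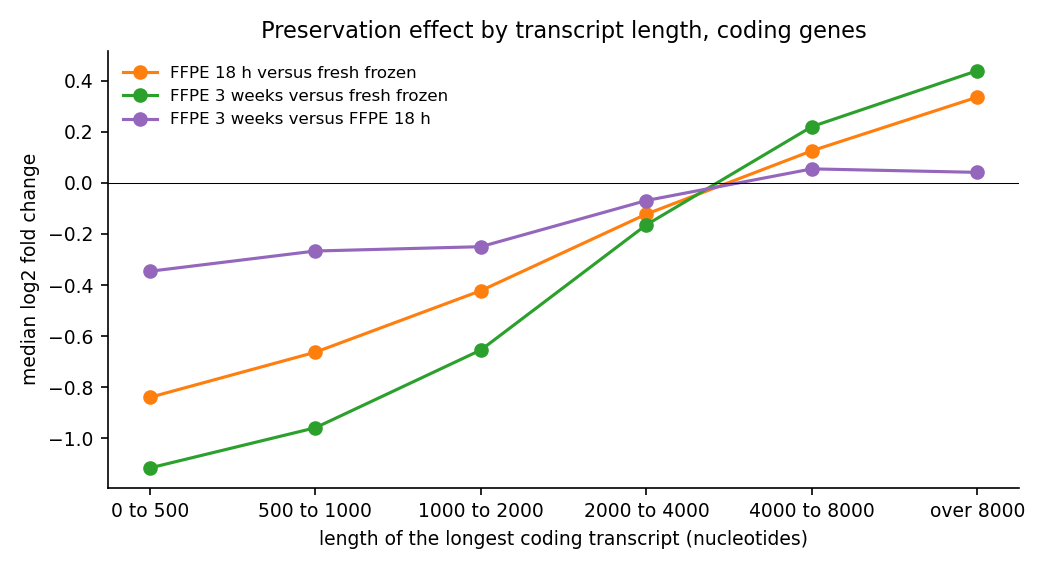
Median log2 fold change between preservations (vertical axis) of coding genes by transcript length class (horizontal axis). In FFPE 18 h against frozen tissue it ran from -0.84 for 23 genes of at most 500 nucleotides to 0.34 for 657 genes above 8000.

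Among coding genes the change with preservation followed transcript length, with Spearman rho across genes of 0.53 for FFPE 18 h against frozen, 0.48 for FFPE 3 weeks against frozen and 0.24 for FFPE 3 weeks against FFPE 18 h. With GC content rho was 0.11, -0.18 and -0.41 in the same order, so it turned sign between FFPE 18 h and FFPE 3 weeks. The ribosomal RNA precursor Rn45s took 0.125% ± 0.0577 of counts in frozen, 1.19% ± 0.191 in FFPE 18 h and 3.78% ± 0.811 in FFPE 3 weeks libraries (SD, n = 8), and albumin 11.6% ± 0.785, 8.90% ± 0.638 and 5.90% ± 0.418. Each of these steps had p = 0.0078 in the exact permutation test, the smallest it can give, and an adjusted p of 0.0094 over 24 tests. At equal depth 14742, 15535 and 13655 genes had a count. With at least 5 counts there were 12299.5, 13141.5 and 12966.8 genes on average, so the order of frozen and FFPE 3 weeks tissue depended on this minimum. The biological coefficient of variation was 0.216 in frozen tissue, 0.145 in FFPE 18 h and 0.469 in FFPE 3 weeks, and it was 0.153 in frozen tissue without control animal 3.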

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

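The tests of the liver itself, of RNA damage, of the calls without control animal 3 and of the effect size, the GC correction and the estimated correlation for the interaction lists were chosen only after the result was seen.

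Named genes held 4 of the 8 values that stood apart from the other 3 of their group by Dixon's criterion. Mmp12 was 0.485 CPM in FFPE 18 h control animal 6, against 0.120 to 0.175 in the others. Cdkn1a was 20.4 CPM in FFPE 3 weeks furan animal 43, against 33.4 to 34.7, so its rise was present there too. Phlda3 was 7.84 CPM in frozen furan animal 43, against 3.95 to 4.47. Atf3 was 16.2 CPM in FFPE 3 weeks furan animal 41, against 8.58 to 9.27. The other 4 values belonged to libraries. Total counts, in megacounts (M), were 25.3 M in FFPE 18 h control animal 3, against 22.9 to 23.3, and 28.1 M in FFPE 18 h furan animal 41, against 23.9 to 24.1. The frozen library of control animal 3 had 0.251% of counts on Rn45s, against 0.0882 to 0.111%, and a mean Spearman correlation with its own group of 0.970, against 0.983 to 0.986. In all 186 groups were examined, 66 of library values and 120 of gene values, and chance alone gives such a value in about 1 in 20 groups, so 8 is no more than chance gives.

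Some gene lists differed in their furan effect between preservations by camera on the interaction, while edgeR called 0 single genes. Between FFPE 18 h and frozen tissue, matrix and stellate activation genes (median difference 0.28, adjusted p = 0.00128) and sinusoidal endothelial markers (0.08, 0.0383) were higher in the fixed tissue. Lower there were immediate early genes (-0.10, 0.0383), oncofetal markers (-0.33, 0.0328), the respiratory chain (-0.06, 0.0328), ribosomal proteins (-0.09, 0.00438), histones (-0.28, 0.00863), other small structured RNAs (-0.28, 0.0328) and major urinary proteins (-0.13, 0.0328). Small nucleolar RNAs had a median difference of 0.00, a mean of -0.13 and adjusted p = 0.00438. Between FFPE 3 weeks and frozen tissue, matrix genes (0.31), sinusoidal endothelial markers (0.11), erythroid markers (-0.65) and other small structured RNAs (1.61) each had adjusted p = 0.0498. Between both fixations, immediate early genes (0.25, adjusted p = 0.0341) and other small structured RNAs (1.66, adjusted p = 6.24e-06) differed. With an estimated correlation 0 of these lists passed. In 35 splits of the animals, the real one included, 1 gave as many lists for FFPE 18 h against frozen (real 10, highest other 7). For FFPE 3 weeks against frozen 1 did (4 and 2), and for both fixations 4 did (2 and 3). The share was thus under 0.05 for the first pair and the second, not for the third. It was the smallest that 35 splits can give. The 4 lists of the second pair lay just under the threshold, so chance is not firmly excluded there. These lists were not tested again without the frozen library of control animal 3.

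Counts of genes with a changed furan effect were compared with splits in the same way, at an unadjusted p below 0.05. As many were found in 8 of 35 splits for FFPE 18 h against frozen (239, highest other 526). For FFPE 3 weeks against frozen they were found in 4 of 35 (585 and 645). For both fixations it was 1 of 35 (766 and 638), the only share under 0.05 and the smallest these splits can give. Without any effect a share of about 0.05 of genes has such a p, and 766 of 14414 tested genes is close to that. After adjustment 0 genes were called, so chance is not excluded for any of these counts.

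The first pattern was that the frozen library of control animal 3 stood apart. Its deviation from the other libraries had an SD 1.71 times that of the highest other control, and 1.59 times after each library's GC trend was removed, so a GC trend was not the whole cause, although 43.7% of the variance of its deviation lay on that trend. In the deviation of the animal's FFPE 18 h piece the correlation with its frozen piece was 0.0245, against 0.459 to 0.688 in the other 7 animals, which argues against a difference of the liver itself. The deviation followed transcript length with a rank correlation of -0.00347, within the range of -0.202 to 0.238 in the other frozen libraries. By this test alone, that argues against damage like that in fixed tissue. Rn45s, which was higher in fixed tissue, goes the other way. It took 0.251% of counts in this library, against 0.0882 to 0.111% in the other frozen controls, so such damage is not excluded. Each of the other 7 animals matched its own frozen piece at 0.459 to 0.688, which argues against a swap between frozen libraries of the series. A swap with a sample from outside the series, a different part of the liver or an error in preparing that library may be the cause and stays open.

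The second pattern was that more genes were called with furan in FFPE 18 h than in frozen tissue, although Cdkn1a, Eda2r and Mmp12 rose by similar folds. Frozen libraries held more counts than FFPE 18 h libraries, 44.3 against 24.4 M on average. Depth could thus only have favoured calls in frozen tissue, and at 1 thinned total the ratio of calls was 5.93. Without control animal 3 in either tissue the ratio was 1.38, which is in line with that frozen library as the main source. Genes called in FFPE 3 weeks had a median log2 change in FFPE 18 h of 0.936 times that in frozen tissue, which argues against a larger effect in fixed tissue. What remains open is the smaller spread of FFPE 18 h libraries, with a biological coefficient of variation of 0.145 against 0.153 in frozen tissue without that animal.

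The third pattern was that gene lists were lower in fixed than in frozen tissue. Transcript length did not account for all of it, since the medians lay below those of random lists matched on length by -0.42 for the respiratory chain, -0.57 for the proteasome and -0.53 for secreted proteins, each outside the range of the random lists. For cytosolic ribosomal proteins the median of -0.44 in FFPE 18 h lay within the length-matched range of -0.62 to -0.35, and that of -0.45 in FFPE 3 weeks lay above the range of -1.02 to -0.54. Matched on abundance, secreted proteins were still lower by -0.23, just outside the range of -0.76 to -0.45. All these random lists were drawn gene by gene, so their ranges leave out correlation between members and may be too narrow. Extraction kit, input, piece of liver and preservation changed together. Cytosolic transcripts may thus be lost in extraction or changed during fixation, or the pieces may differ, and no biological explanation was tested.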

How the results depend on the processing

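The GC correction, the block with length and GC correction, the lists with a block, with GC correction or without a library, and the estimated correlation for interactions were chosen only after the results were seen.

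Among named furan genes called here or under an alternative, 0 reversed direction. Gene lists that did not pass in either form did turn: with GC correction matrix, circadian clock and other small RNA genes in frozen tissue, long nuclear RNAs in frozen and FFPE 18 h tissue and macrophage markers in FFPE 3 weeks. Without frozen control animal 3 matrix genes, periportal markers, microRNA precursors, other small RNAs and long nuclear RNAs turned, and with the animal as a block inflammatory cytokines did for FFPE 3 weeks against frozen. Some lists passed under an alternative alone. Secreted proteins did in frozen tissue without control animal 3 (adjusted p = 0.0200), and with GC correction inflammatory cytokines did in FFPE 18 h (0.0458) and FFPE 3 weeks (0.0483) and ribosomal proteins in FFPE 3 weeks (0.0483), while other small RNAs in FFPE 18 h did not pass (0.0895). With the animal as a block, cell cycle genes (0.0280), quiescent stellate markers (0.0421) and the circadian clock (0.0404) passed for FFPE 18 h against frozen, and pericentral markers and histones (0.0433 each) for FFPE 3 weeks against FFPE 18 h. Of the called named genes 27 of 66 frozen calls, 49 of 112 in FFPE 18 h and 33 of 51 in FFPE 3 weeks were called by every alternative. With DESeq2 the frozen furan calls were 1066, of which 391 are among the 392, the overlaps of frozen calls with FFPE 18 h and FFPE 3 weeks were 823 and 264, and the interactions of FFPE 3 weeks with frozen and with FFPE 18 h had 9 and 26 calls. With GC correction frozen calls were 1009, sharing 384, and the overlaps 786 and 212. A fold of at least 1.5 left 589 calls in FFPE 18 h and 222 in FFPE 3 weeks with furan, 3977 for FFPE 18 h against frozen and 2293 for FFPE 3 weeks against FFPE 18 h, as this alternative's own construction removes small changes. A single fit over all 24 libraries, which shares 1 dispersion per gene, gave 305 furan calls in FFPE 18 h, 1549 in FFPE 3 weeks, 5224 for FFPE 18 h against frozen, and 4 and 5 for the interactions of FFPE 3 weeks with frozen and with FFPE 18 h. With no low-count filter the correlations of fold changes were 0.193, 0.121 and 0.113, and thinned to the smallest total, which tests fewer genes, they were 0.743, 0.489 and 0.477. With an estimated correlation 2, 1 and 2 lists passed for furan in frozen, FFPE 18 h and FFPE 3 weeks, 4, 8 and 3 for the preservation comparisons and 0, 0 and 0 for the interactions. Except where the construction shows it, the cause was not tested.

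Leaving out single libraries, frozen calls ran from 99 (without furan animal 44) to 1148 (without control animal 3), with 105 without furan animal 43, 160 without 42, 174 without 41, 146 without control animal 4 and 182 without 6. FFPE 18 h calls ran from 1582 to 2061, and FFPE 3 weeks calls from 218 (without furan animal 44) to 280. Preservation calls ran from 7521 to 8907, 6355 to 7114 and 4112 to 4999. Interaction calls were 0 throughout for FFPE 18 h against frozen with edgeR (239 at an unadjusted p below 0.05, 0 with DESeq2). They ran from 0 to 4 for FFPE 3 weeks against frozen (4 without FFPE 3 weeks furan animal 43, 2 without control animal 3 or 4) and from 0 to 2 for FFPE 3 weeks against FFPE 18 h (2 without FFPE 3 weeks control animal 3 or 4, 1 without furan animal 41). For overlaps and correlations the animal was left out of every preservation. Overlaps of frozen with FFPE 18 h ran from 95 (without furan animal 44) to 761 (without control animal 3), with 100, 150, 157, 135 and 172 without furan animals 43, 42 and 41 and control animals 4 and 6, and with only the frozen library of control animal 3 left out 852 frozen calls were also called in FFPE 18 h. They ran from 41 (without furan animal 44) to 186 (without control animal 3) for frozen with FFPE 3 weeks, with 44, 63, 59, 57 and 77 in the same order, and from 186 (without furan animal 44) to 245 for both fixations. Correlations ran from 0.634 to 0.672, 0.344 to 0.392 and 0.338 to 0.367.

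Other counts of calls lay within 1.5 times the reported ones: with the replicate block they were 8522, 6719 and 5162 for preservation, with the replicate block and length and GC correction 8223, 6073 and 4159, and with DESeq2 size factors the furan calls were 384, 2198 and 333. Thinned to the smallest total, furan calls were 268 in frozen, 1590 in FFPE 18 h and 320 in FFPE 3 weeks. At equal depth frozen tissue thus had fewer calls than FFPE 3 weeks with the frozen library of control animal 3 included. At full depth frozen calls rose from 392 to 1148 without that library, and the thinned fit was not repeated without it. The order at equal depth may therefore rest on that library.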

Other observations

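The classes below were defined after the FFPE 18 h calls were seen, and all of their tests were written before the class medians in frozen tissue were computed. Frozen fold changes of single genes came from the same run as the FFPE 18 h calls, so they existed by then. The animals are the same in each preservation, so the frozen values are no independent evidence.

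Ribosome assembly factors were higher in 21 of 55 cases in FFPE 18 h, with a median log2 fold change of 0.29, and Utp20 rose by 0.60 ± 0.07 and Rrp12 by 0.94 ± 0.15. In frozen tissue 6 rose and their median was 0.30, above the random range of -0.10 to 0.10, and in FFPE 3 weeks it was 0.33 with 0 called by edgeR. Importins and exportins rose in 9 of 25 cases in FFPE 18 h, with Xpo1, the main nuclear export receptor, at 0.59 ± 0.06 and Kpnb1 at 0.52 ± 0.07, in 2 of 25 in frozen and in 2 of 24 in FFPE 3 weeks tissue, with medians of 0.23 in frozen and 0.22 in FFPE 3 weeks. Cytosolic tRNA synthetases rose in 7 of 20 cases in FFPE 18 h, 2 in frozen and 0 in FFPE 3 weeks, with Rars at 0.56 ± 0.08 and Gars at 0.55 ± 0.07, and their median was 0.20 in frozen tissue, above the range of -0.11 to 0.15, and 0.13 in FFPE 3 weeks, within the random range.

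Coagulation factors and inhibitors fell in 12 of 24 cases in FFPE 18 h, 0 of 24 in frozen and 2 of 24 in FFPE 3 weeks, with F7 at -0.63 ± 0.07 and Proc at -0.58 ± 0.06, and their medians were -0.17 in frozen, -0.19 in FFPE 18 h and -0.21 in FFPE 3 weeks tissue. A class of SR proteins, CLK kinases and other genes tied to splicing had 5 of 26 lower in FFPE 18 h, 1 in frozen and 4 in FFPE 3 weeks. Of the 5, Srsf5 (-0.57 ± 0.06) is an SR protein, and Ddx17, a helicase, Leng8, Luc7l2 and Rsrp1 are among the other genes. Their median there was -0.02, within the random range, and in frozen tissue it was 0.0627, so the class as a whole did not move the same way.

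Pieces of the same liver were recognised by expression. Over 4317 genes, the deviations of an animal's FFPE 18 h library correlated best with the frozen library of the same number in 7 of 8 cases, those of FFPE 3 weeks with FFPE 18 h in 8 of 8 and with frozen in 6 of 8. Dmbt1 in FFPE 18 h ran from 1.03 CPM in control animal 4 to 186 CPM in control animal 2, without TMM normalization.

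The furan results were compared with splits of the 8 animals. The 392, 2208 and 335 called genes were reached in 1 of 35 splits each, the real one, with 1 call in the highest other. The other splits mix furan and control animals, which widens the spread within their groups and lowers their calls. The share was under 0.05 and the smallest that 35 splits can give, so it argues against chance without firmly excluding it. The same holds for the correlations of 0.70, 0.44 and 0.44 (highest others 0.494, 0.243 and 0.239), each reached in 1 of 35 splits. The overlaps of 331, 136 and 285 were also reached in 1 of 35 splits each (highest other 0), but the other splits had 0 or 1 calls per preservation, which fixed their overlap, so this comparison decides nothing. For the number of lists past the threshold chance cannot be excluded: 16 lists in frozen tissue were reached in 2 of 35 splits (highest other 17), 14 in FFPE 18 h in 7 of 35 (18) and 10 in FFPE 3 weeks in 2 of 35 (11). The other splits that reached these counts exchanged 1 animal of each treatment and so kept part of the furan contrast, and the 18 mixed splits gave at most 14, 11 and 7 lists, too few splits for a share under 0.05. For preservation, 100 splits gave 8006, 6952 and 4664 calls in 1 each (highest others 5821, 4030 and 2247). This share is the smallest that 100 splits can give, and it argues against chance. The highest of the other splits exchanged the labels of 1 animal. As many as 21, 24 and 12 lists were reached in 23, 5 and 9 of 100 splits (highest others 25, 26 and 13), so over all splits chance cannot be excluded for these counts. The splits that reached them exchanged 1 to 3 or 6 to 7 animals and so kept part of the preservation difference, and the 26 splits that exchanged 4 animals gave at most 10, 4 and 4 lists.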
